A study of Mus musculus with 48 samples.

How the data were processed

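The series holds mRNA sequencing of 48 mouse libraries: 30 from epididymal white adipose tissue and 18 from cells labelled as F4/80+, CD11b+ and CD64+ macrophages of the same tissue. Groups follow the labels for tissue, genotype and diet. Per the labels, adipose tissue libraries were made with a stranded mRNA kit from 500 ng of total RNA, and macrophage libraries from 1 to 5 ng with an ultra-low-input cDNA kit that marks no strand. The title prefixes divide the libraries into 4 sets, 1 per tissue and diet, so diet coincides with library set.

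The authors deposited raw read counts per gene for each library, made with Trim Galore 0.6.0 and STAR 2.7.8a on mm10. These counts are not normalized. The annotation release behind them is not given in the sources used here. The files hold 55471 genes, of which 55144 were given a symbol. Gene positions, GC content and transcript lengths came from the GENCODE vM21 annotation of GRCm38. For adipose tissue the strand column with the larger total was used, and for macrophage-labelled libraries the unstranded column. Rows for unmapped, multimapping, unassigned and ambiguous reads were left out of the gene counts.

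Each comparison was fitted in R 4.3.3 with edgeR 4.0.16: filterByExpr on the groups fitted, TMM normalization, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. All tests are two-sided. Genotype labels were compared within tissue and diet, diets within tissue and genotype label, and the interaction in 1 fit of the 4 groups of a tissue. The SE of a log2 fold change is its absolute value divided by the square root of its F statistic. CPM values use TMM factors over all libraries of a tissue. Total gene counts per library ran from 17.4 to 59.8 M.

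A set of 34 gene lists (cell types, metabolic pathways and stress responses) was fixed together with the design, the named-gene rule and the alternatives before the data were examined. Lists with at least 4 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a comparison, with an estimated correlation and with fry as alternatives. Members were counted by the gene test over all genes and adjusted over the list alone. Named genes are Txnip, the 5 largest rises and falls among called genes with a mean of at least 2 CPM and an ordinary gene symbol, and up to 3 called members of a list, less some genes that are not reported here.

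Alternatives were DESeq2 1.42.0 (size factors, and its Wald test), limma-voom with sample quality weights, no low-count filter, all 4 groups of a tissue in one fit, the replicate number as a block, the unstranded column for adipose tissue, and leaving out 1 library at a time where run. Offsets for GC content, and for GC content and length, from a smooth with a span of 0.3, and fits without the macrophage-labelled ketogenic libraries of doubtful label were added after seeing the data. A comparison of the diets with both genotype labels together was added then as well. The replicate numbers in the titles were checked for pairing between groups. In eWAT 6 of 8 ketogenic and 1 of 7 control-diet libraries were most like the library of the other genotype label with their own number, and 3 of 6 macrophage-labelled control-diet libraries were. The rule set for pairing was not met, and no block was fitted in the results given. In the eWAT ketogenic comparison 7 of 8 pairs of the same number had a correlation above 0.1. In the macrophage-labelled control-diet comparison 5 of 6 did, and in the eWAT control-diet comparison 4 of 7. Pairing is therefore not excluded. The counts with a block are given with the eWAT ketogenic and the macrophage-labelled control-diet comparisons. Each replicate pair was checked for copies, and none was found.

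The pipeline was tested on simulated data, with counts drawn from a negative binomial model of each comparison's means and dispersions and 200 genes changed. In the adipose tissue control-diet comparison edgeR recovered 56.7% of genes changed 1.5-fold, 82.1% at 2-fold and 92.4% at 4-fold, with 4 false calls. In the adipose tissue ketogenic comparison it recovered 58.2%, 91.0% and 95.5% with 9 false calls, and in the macrophage-labelled control-diet comparison 47.8%, 74.6% and 95.5% with 7. In the macrophage-labelled ketogenic comparison of 3 against 3 libraries it recovered 55.2%, 67.2% and 87.9% with 12, and in the macrophage-labelled interaction 16.4%, 53.7% and 68.2% with 7. A simulated tilt with GC content gave 1063 false calls in the adipose tissue control-diet comparison without the GC offset and 8 with it. Genes were drawn independently, and the tilt was the same in each library labelled knockout. The simulated data thus held no correlation between genes and no other structure among libraries. Their false calls do not give the rate in the real data.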

Results

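RNA was sequenced from mouse epididymal white adipose tissue (eWAT) and from cells sorted from it as F4/80+, CD11b+ and CD64+ macrophages, in animals labelled wild type or adipose-specific Txnip knockout and fed a control or a ketogenic diet. The 48 libraries form 8 groups. On the control diet there were 7 eWAT libraries per genotype and 6 macrophage-labelled libraries per genotype, and on the ketogenic diet 8 and 3 per genotype. Gene counts per library ranged from 34.7 to 59.8 M (eWAT, wild type, control diet), 35.1 to 51.7 M (eWAT, knockout, control), 17.4 to 25.1 M (eWAT, wild type, ketogenic) and 21.0 to 39.0 M (eWAT, knockout, ketogenic). In the macrophage-labelled groups they ranged, in the same order, from 36.9 to 47.3, 42.4 to 47.0, 44.7 to 59.7 and 43.8 to 53.2 M. Levels are given as TMM-normalized CPM (mean ± SD), and changes as fitted log2 fold changes ± SE with edgeR adjusted p-values. The labels do not say that each library comes from a different animal.

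Txnip, the gene named as deleted, encodes an arrestin-like protein that restrains glucose uptake and binds thioredoxin (ENSMUSG00000038393, GRCm38 chromosome 3, 96557957 to 96561883). In eWAT on the control diet its level was higher in the libraries labelled knockout, from 1702 ± 189.7 to 2705 ± 281 CPM between wild type and knockout label (n = 7 and 7, log2 fold change 0.69 ± 0.09, adjusted p = 0.00085), and all 7 libraries labelled knockout lay above all 7 labelled wild type. On the ketogenic diet the change was 0.35 ± 0.09 (1796 ± 282 to 2312 ± 241 CPM, n = 8 and 8, adjusted p = 0.044). That call ended without the low-count filter (adjusted p = 0.057) and when any of wild type replicates 2, 3, 5, 7 and 8 or knockout replicates 1, 3, 4, 6, 7 and 8 was left out (adjusted p from 0.053 to 0.084). It stayed in the other settings that left out no library, with adjusted p from 0.0023 (replicate block) to 0.044 (DESeq2 size factors). In the macrophage-labelled libraries Txnip differed by 0.08 ± 0.11 on the control diet (adjusted p = 0.77) and -0.02 ± 0.13 on the ketogenic diet (adjusted p = 1.00), without passing the test. The rises in eWAT go against the label, so every genotype comparison here reads as libraries labelled knockout against libraries labelled wild type. Counts over a whole gene cannot show the loss of part of it.

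**Figure D1:**
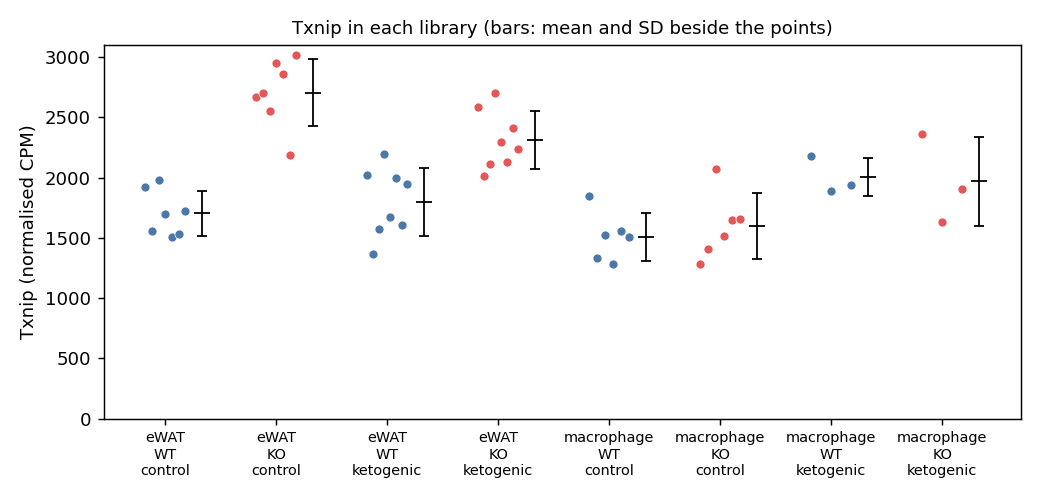
Level of Txnip (CPM, vertical axis) in each of the 48 libraries by group, each point a library and each bar the group mean with SD. On the control diet the 7 eWAT libraries labelled knockout average 2705 CPM and all lie above the 7 labelled wild type, which average 1702 CPM.

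The first comparison asks what the knockout label goes with in eWAT on the control diet. Of 18 genes of oxidative phosphorylation 7 were lower and none higher in the libraries labelled knockout (n = 7 and 7), and 9 were lower adjusted over the list alone. Among them were Sdhb of complex II (-0.42 ± 0.05), Uqcrc1 of complex III (-0.46 ± 0.08) and Ndufv1 of complex I (-0.44 ± 0.08). Fatty acid oxidation followed with 4 of 18 members lower and 6 adjusted over the list alone: Acads, a short-chain acyl-CoA dehydrogenase (-0.95 ± 0.14), Slc25a20, the carnitine-acylcarnitine carrier (-0.23 ± 0.05), and Hadh (-0.38 ± 0.09) are examples. Adipocyte genes were lower in 6 of 18 (6 also adjusted over the list alone), with Cidec (-0.61 ± 0.11) and Plin1 (-0.42 ± 0.08), which coat lipid droplets, and Cfd, the secreted factor adipsin (-0.99 ± 0.21). Of 14 extracellular matrix genes 6 were lower, 7 adjusted over the list alone, with 1 higher there. Col3a1 (-0.50 ± 0.11), Col6a3 (-0.43 ± 0.11) and Col5a1 (-0.63 ± 0.18) encode collagen chains. Immediate early and dissociation-stress genes were lower in 5 of 13 and higher in none. Their list did not pass its test (adjusted p = 0.11; 0.83 with an estimated correlation).

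Lipogenic genes on the same diet went both ways. Scd1, which desaturates stearoyl-CoA, rose from 28466 ± 4801 to 49748 ± 6428 CPM between wild type and knockout label (0.83 ± 0.12), and Acaca, which makes malonyl-CoA, by 0.84 ± 0.12, while Srebf1, a regulator of lipogenic genes, was lower (-0.92 ± 0.17). The list of 16 had 2 members higher and 2 lower (2 and 3 adjusted over the list alone) and did not pass its test (adjusted p = 0.87; 0.94 with an estimated correlation). Arrdc4, a related arrestin gene that glucose induces, was higher (0.31 ± 0.07, adjusted p = 0.0086). The endothelial genes Emcn (0.34 ± 0.06), Pecam1 (0.29 ± 0.06) and Tek (0.27 ± 0.06) were among 4 of 10 endothelial markers that were higher, with 4 adjusted over the list alone. Among called genes with a mean of at least 2 CPM and an ordinary symbol, as in each ranking below, the largest rises were in Ntrk3, a neurotrophin receptor (1.58 ± 0.18), Inmt, a methyltransferase (1.21 ± 0.39), AW822252 (1.2 ± 0.36), the leukocyte receptor Lilra5 (1.16 ± 0.22) and the zinc-finger gene Zfp949 (1.13 ± 0.07). Largest among the falls were the histone gene Hist1h4h (-2.28 ± 0.55), the potassium channel gene Kcnh2 (-2.27 ± 0.47), the interferon-induced Ifi27l2a (-1.82 ± 0.27), Sez6l (-1.78 ± 0.45) and the cytokine receptor gene Crlf2 (-1.72 ± 0.40).

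In all, 738 genes were higher and 1939 lower of 16746 tested in this comparison, 341 and 1475 without the low-count filter and 1314 and 2328 with the DESeq2 Wald test. The list tests gave adjusted p = 0.00018 for oxidative phosphorylation, 0.016 for adipocyte genes, 0.017 for fatty acid oxidation, 0.038 for extracellular matrix and 0.089 for endothelial genes. With an estimated correlation these became adjusted p = 0.73, 0.73, 0.73, 0.83 and 0.73. The change per gene followed GC content (Spearman correlation -0.57 across genes, which are not independent replicates), and of the quintile of genes with the highest GC content 6 were higher and 1264 lower. The slope of expression on GC content, relative to the mean of all eWAT libraries, was 0.24 ± 0.09 log2 units per 0.1 of GC in the libraries labelled wild type (n = 7) and -0.03 ± 0.14 in those labelled knockout (n = 7). It fell with each replicate number in the wild type label, from 0.35 in replicate 1 to 0.12 in replicate 7, and was 0.10 in knockout replicate 1. The other knockout libraries ran from -0.28 to 0.17 without that order. An effect of sample order was not separated from the label. With a GC offset, chosen after seeing the data, 1211 genes passed, 897 of them also without it. The calls of Cfd, Col5a1, Col6a3, Crlf2, Inmt and Plin1 then ended. The lists of adipocyte and extracellular matrix genes each came to adjusted p = 0.060, and endothelial genes and fatty acid oxidation each came to adjusted p = 0.00017. Inmt lost its call without any single one of wild type replicates 1 to 6 and knockout replicates 2, 4, 5 and 7 (adjusted p from 0.060 to 0.11). AW822252 lost its call without wild type replicates 1, 2 and 5 or knockout replicates 1, 3, 4 and 6 (0.051 to 0.066), and Col5a1 without wild type replicates 1 and 2 or knockout replicate 5 (0.052 to 0.058). Inmt, AW822252, Col5a1, Hist1h4h and Sez6l also lost theirs without the low-count filter, and Col3a1 and Col6a3 with all 4 eWAT groups in one fit.

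**Figure D2:**
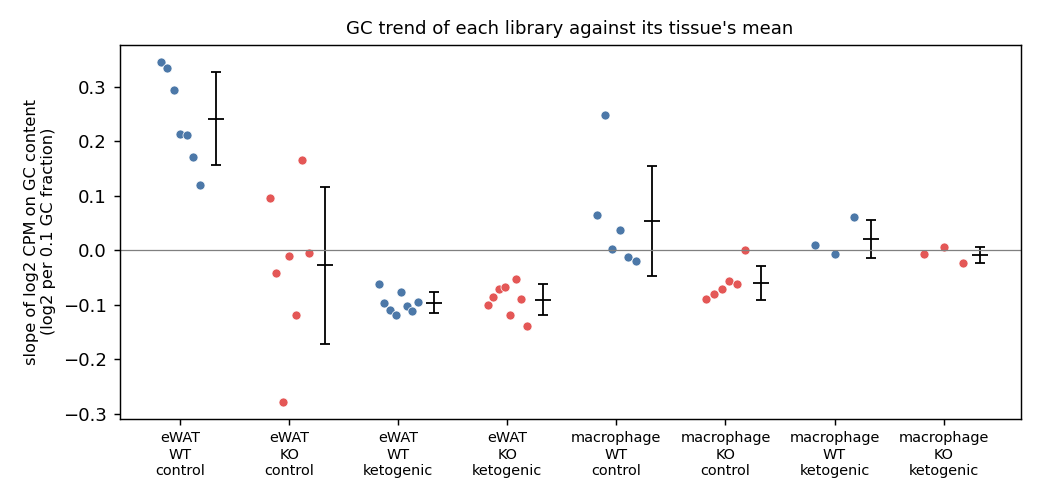
Slope of log2 expression on GC content (log2 units per 0.1 of GC, vertical axis), relative to the mean of its tissue, for each library by group, each point a library and each bar the group mean with SD. The eWAT control-diet libraries labelled wild type average 0.24 and those labelled knockout -0.03, with a spread from -0.28 to 0.17 in the latter, while the ketogenic eWAT groups average -0.10 and -0.09.

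On the ketogenic diet eWAT libraries labelled knockout (n = 8) were compared with those labelled wild type (n = 8). Arg1, which breaks down arginine, went from 1.17 ± 0.812 to 7.50 ± 4.97 CPM (2.67 ± 0.53), and Spp1, the matrix protein osteopontin, from 0.782 ± 0.552 to 3.29 ± 2.21 CPM (2.08 ± 0.52). The chemokine gene Ccl22 went from 1.01 ± 0.351 to 3.89 ± 1.87 CPM (1.94 ± 0.34). Ptx3, a soluble pattern receptor, and Il1rn, the interleukin-1 receptor antagonist, rose by 1.87 ± 0.50 and 1.56 ± 0.40. Of 15 pan-macrophage markers none passed over all genes and 12 were higher adjusted over the list alone (list adjusted p = 6.8e-09; 0.15 with an estimated correlation). Lipid-associated macrophage genes were higher in 2 of 15, and 9 higher with 1 lower adjusted over the list alone (4.4e-05; adjusted p = 0.29 with an estimated correlation), with the galectin gene Lgals3 (0.60 ± 0.15) beside Spp1. Both resident macrophage calls, Lyve1 (0.36 ± 0.07) and Mrc1 (0.28 ± 0.07), encode scavenging surface receptors (2 of 14 higher, 2 adjusted over the list alone, 0.0029; adjusted p = 0.32 with an estimated correlation). Antigen presentation by MHC class II had 1 of 8 members higher, H2-DMb1 (0.70 ± 0.18), and 8 adjusted over the list alone (2.0e-05; adjusted p = 0.29 with an estimated correlation). The monocyte chemokine receptor gene Ccr2 (0.90 ± 0.21), the prostaglandin synthase gene Ptgs2 (0.83 ± 0.22) and the cystine transporter gene Slc7a11 (1.71 ± 0.38) were higher too. Inflammatory cytokine genes were higher in 1 of 12 (6 adjusted over the list alone, 0.00048; adjusted p = 0.15 with an estimated correlation). Mesothelial markers had no member past the test and a list adjusted p = 0.00064 towards the knockout label (0.39 with an estimated correlation).

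In the same comparison fatty acid oxidation had 4 of 18 members lower with the knockout label, 14 adjusted over the list alone, among them Slc25a20 (-0.28 ± 0.07), the long-chain dehydrogenase gene Acadl (-0.37 ± 0.09) and the peroxisomal Ehhadh (-0.45 ± 0.12). Cholesterol synthesis had 2 of 14 lower and 9 adjusted over the list alone, with Insig1, which holds back sterol-regulated transcription, from 316 ± 92.5 to 127 ± 29.6 CPM (-1.33 ± 0.17) and Msmo1, a sterol demethylase (-0.35 ± 0.09). Acsl1, which activates fatty acids (-0.57 ± 0.12), and Cidec (-0.34 ± 0.08) were lower among 18 adipocyte genes (4 adjusted over the list alone). Of 5 thermogenic genes Cidea (-1.74 ± 0.29) and Cox8b (-0.85 ± 0.17) were lower (3 adjusted over the list alone), and of 16 lipogenic genes the citrate carrier gene Slc25a1 (-0.42 ± 0.10) and Pnpla3 (-0.91 ± 0.22) were (4 adjusted over the list alone). Oxidative phosphorylation had no member past the test over all genes and 11 of 18 lower adjusted over the list alone. Beyond Insig1, and among genes with a mean of at least 2 CPM, which leaves out Cidea, the largest falls were in Sez6l (-1.76 ± 0.37), the imprinted gene Nap1l5 (-1.35 ± 0.16), Efcab8 (-1.28 ± 0.22) and Kcnh2 (-1.26 ± 0.23).

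Over all genes 226 were higher and 286 lower of 15225 tested on the ketogenic diet. With the replicate number as a block 775 were higher and 811 lower, and the call of Ptx3 ended. The DESeq2 Wald test gave 526 and 521, and the fit without the low-count filter 151 and 180. The lists came to adjusted p = 5.1e-09 for fatty acid oxidation, 1.4e-08 for cholesterol synthesis, 2.7e-08 for oxidative phosphorylation, 1.2e-05 for adipocyte, 0.00027 for thermogenic and 0.017 for lipogenic genes. They came to adjusted p = 0.15, 0.15, 0.34, 0.28, 0.14 and 0.43 with an estimated correlation. Single libraries moved the count of 512: it was 788 without wild type replicate 1, 205 without knockout replicate 6, and 278, 339, 286, 287 and 272 without wild type replicates 2, 3, 5, 7 and 8. Without knockout replicates 1, 2, 3 and 4 it was 290, 334, 262 and 286. Of the 28 genes named for this comparison 11 kept their call in all 16 runs that left out 1 library, and 17 lost it in at least 1 (adjusted p from 0.050 to 0.11), without a change of direction. Only without wild type replicate 1 did all 28 keep it. The call of Arg1 ended under limma-voom, as did those of Ccl22, Slc7a11, Il1rn, Lgals3, Ptx3 and Spp1, and 13 of the 28 ended without the low-count filter. With all 4 eWAT groups in one fit the calls of Cox8b, Ehhadh, Il1rn, Lgals3, Lyve1, Mrc1, Ptgs2, Ptx3 and Spp1 ended. Of the genes called on the control diet, 45 higher and 107 lower were called in the same direction on the ketogenic diet. There 10.5 and 35.5 would be shared if the calls were independent, and 1 and 2 went the opposite way (15206 genes tested in both; Fisher's exact test, two-sided, p = 7.1e-17 and 8.6e-28, across genes, which are not independent replicates).

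**Figure D3:**
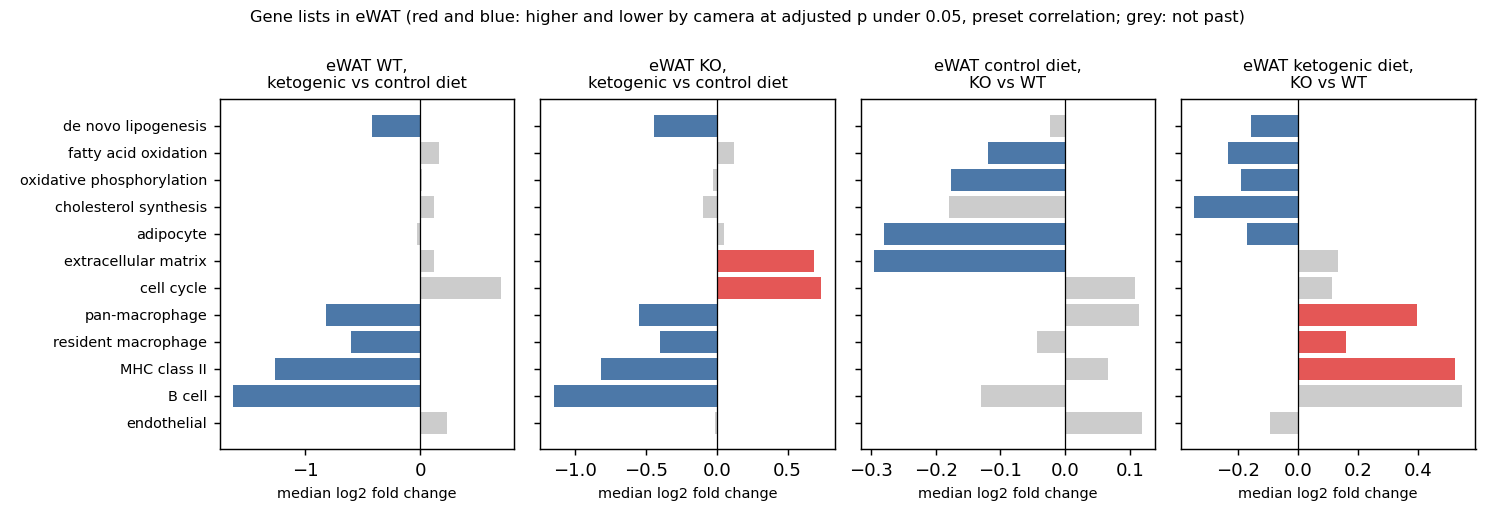
Median log2 fold change of the members of selected gene lists (horizontal axis, log2 units) in the 4 eWAT comparisons of diet and of genotype label, 1 panel each, with horizontal scales that differ between panels and coloured bars for lists past the test at the preset correlation. In eWAT libraries labelled knockout on the ketogenic diet the pan-macrophage list has a median of 0.40 and the fatty acid oxidation list one of -0.23.

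The diet comparisons in eWAT ask what the ketogenic diet goes with in each genotype label. In libraries labelled wild type (8 ketogenic, 7 control) all 9 MHC class II genes were lower on the ketogenic diet (9 adjusted over the list alone), with the invariant chain gene Cd74 from 585 ± 59.6 to 219.6 ± 36.7 CPM (-1.30 ± 0.09), H2-DMa (-1.44 ± 0.11) and H2-DMb1 (-1.15 ± 0.10). Of 15 pan-macrophage markers 13 were lower (13 adjusted over the list alone), such as the complement gene C1qb (-1.04 ± 0.10), the growth factor receptor gene Csf1r (-0.75 ± 0.07) and the Fc receptor chain gene Fcer1g (-1.19 ± 0.12). Of 14 resident macrophage genes 10 were lower (10 adjusted over the list alone), including Cbr2 (-0.93 ± 0.06), Gas6 (-1.64 ± 0.15) and Clec10a (-0.75 ± 0.07). B cell genes were lower in 11 of 12 (11 adjusted over the list alone), including Ighd (-1.53 ± 0.27), Cd79b (-1.99 ± 0.43) and Cd22 (-2.12 ± 0.43). Mesothelial markers, of another cell type, had a median over the list of 28.3 ± 10.7 CPM on the control and 14.7 ± 6.44 CPM on the ketogenic diet. Fatty acid synthesis was lower in 10 and higher in 2 of 16 (the same numbers adjusted over the list alone): Fasn, fatty acid synthase, went from 5224 ± 1465 to 926 ± 299 CPM (-2.38 ± 0.21), Acly, which makes cytosolic acetyl-CoA, changed by -1.92 ± 0.17 and transketolase, Tkt, by -1.63 ± 0.12.

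Fatty acid oxidation genes in the libraries labelled wild type were higher in 9 of 18 and lower in 1 (9 and 1 adjusted over the list alone), among them Acadl (0.81 ± 0.08), Etfdh (0.43 ± 0.06) and Hadhb (0.44 ± 0.07). That list did not pass its test (adjusted p = 0.087; 0.94 with an estimated correlation). Insig1 rose by 1.75 ± 0.19. The largest rises were in the imprinted gene Zim1 (2.52 ± 0.37), Mageb18 (2.46 ± 0.20), Arxes1 (2.12 ± 0.15), the collagen gene Col12a1 (2.09 ± 0.26) and Crtac1 (2.07 ± 0.28). Besides Fasn and Cd22, the largest falls at a mean of at least 2 CPM were in the cytochrome gene Cyp2f2 (-4.57 ± 0.35), Inmt (-3.10 ± 0.39) and Card14 (-2.54 ± 0.32). Txnip differed by 0.19 ± 0.10 (adjusted p = 0.10). Of 15569 genes tested 4167 were higher and 4206 lower. List tests gave adjusted p = 1.2e-09 for MHC class II, 4.7e-07 for pan-macrophage, 3.2e-05 for resident macrophage, 0.0017 for lipogenic and 0.014 for B cell genes. These became adjusted p = 0.26, 0.57, 0.57, 0.66 and 0.94 with an estimated correlation. By the title prefixes each diet has its own set of libraries in both tissues, so diet and library set cannot be told apart in any diet comparison. The changes also followed GC content here (Spearman correlation -0.54 across genes, 130 higher and 1792 lower in the highest quintile). Of the called genes 4707 passed both with and without a GC offset. The call of Hadhb ended with it and the list of fatty acid oxidation came to adjusted p = 0.0038.

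In libraries labelled knockout (8 ketogenic, 7 control) lipogenic genes fell as well, 9 of 16 lower and 2 higher (9 and 2 adjusted over the list alone), with Fasn (-2.54 ± 0.22), Acaca (-1.85 ± 0.11) and Thrsp, a lipogenic regulator (-1.95 ± 0.14). MHC class II genes were lower in 8 of 9 (9 adjusted over the list alone), such as H2-Aa (-0.99 ± 0.16) and Cd74 (-0.99 ± 0.17). Pan-macrophage markers were lower in 9 of 15 (10), such as Cd14 (-0.66 ± 0.08), Fcer1g (-0.95 ± 0.16) and Csf1r (-0.59 ± 0.11), and B cell genes were in 9 of 12 (10), such as Ighd (-1.45 ± 0.28) and Fcer2a (-2.04 ± 0.41). Resident macrophage genes were lower in 7 of 14 with 1 higher (8 and 1 adjusted over the list alone), Gas6 (-1.32 ± 0.09) among them. Lysosomal genes were lower in 10 of 15 with 2 higher (10 and 2), the protease gene Ctsd (-0.83 ± 0.11) among them. Extracellular matrix genes were higher in 10 of 14 (10 adjusted over the list alone), with the crosslinking enzyme gene Lox (0.52 ± 0.08) and the collagen genes Col6a3 (0.84 ± 0.14) and Col6a2 (1.19 ± 0.20). Cell cycle genes were higher in 9 of 12 (9), with Top2a (1.29 ± 0.18), Mki67 (1.35 ± 0.19) and Ccna2 (1.22 ± 0.21). Pdk4, which slows glucose oxidation, rose by 1.02 ± 0.14.

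Among the largest rises in these libraries were Scand1 (3.28 ± 0.21), Col12a1 (2.64 ± 0.34), Crtac1 (2.45 ± 0.35) and Mageb18 (2.36 ± 0.26). Besides Fasn the largest falls were in Cyp2f2 (-5.00 ± 0.50), Inmt (-4.48 ± 0.45), Serpina3k (-3.39 ± 0.61) and Lrtm1 (-3.13 ± 0.53). Txnip differed by -0.19 ± 0.08 (adjusted p = 0.078), and passed the test under limma-voom (adjusted p = 0.021) and without the low-count filter (0.047), while with a GC offset it came to 0.17 and with one for GC and length to 0.33. Of 16483 genes tested 3267 were higher and 3251 lower. The list tests gave adjusted p = 1.9e-08 for lipogenic, 0.00023 for matrix, 0.00037 for cell cycle, 0.00071 for MHC class II, 0.0020 for resident macrophage, 0.0020 for pan-macrophage, 0.0031 for B cell and 0.0083 for lysosomal genes. They gave, with an estimated correlation, adjusted p = 0.42 for lipogenic genes and 0.75 for each of the others. Called in both genotype labels in the same direction were 2442 genes higher and 2024 lower, where 866 and 847 would be shared if the calls were independent, and 102 went opposite ways.

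The difference between the diets in the genotype effect was tested as an interaction in eWAT (30 libraries), written as the ketogenic minus the control effect of the knockout label. Arg1 (2.83 ± 0.72), Scand1 (2.38 ± 0.54), Hist1h4h (2.20 ± 0.55), the immediate early gene Junb (1.98 ± 0.37) and Crlf2 (1.76 ± 0.41) had the largest positive values. Among the largest negative values were Rwdd3 (-1.31 ± 0.42), Insig1 (-1.04 ± 0.24), Nap1l5 (-0.98 ± 0.31) and Mbnl3 (-0.84 ± 0.26). Pan-macrophage genes had 3 of 15 positive calls (4 adjusted over the list alone), the complement genes C1qa (0.88 ± 0.19), C1qc (0.86 ± 0.19) and C1qb (0.68 ± 0.15). The endothelial genes Kdr (-0.47 ± 0.11) and Emcn (-0.31 ± 0.08) were negative among 10 (4 adjusted over the list alone), and cholesterol synthesis had 3 of 14 negative calls (3 adjusted over the list alone), Msmo1 (-0.51 ± 0.13) beside Insig1. Txnip had -0.34 ± 0.13 (adjusted p = 0.10), which passed under DESeq2 (adjusted p = 0.040). There were 1193 positive and 232 negative calls of 17140 genes tested, and 156 and 96 with a GC offset. The split was 1048 and 71 without the low-count filter, 1326 and 152 with the unstranded column, 1021 and 416 with DESeq2 size factors and 1297 and 688 with its Wald test. The list tests gave adjusted p = 0.016 for pan-macrophage, 0.021 for cholesterol and 0.027 for endothelial genes, and each came to adjusted p = 1.00 with an estimated correlation. The values followed GC content (Spearman correlation 0.50 across genes, 910 positive and 4 negative in the highest quintile), and with a GC offset 252 genes passed, 183 of them also without it. Of the 15 genes named here with a call, Arg1, Junb, Insig1 and Kdr kept it with the offset, while Arg1, Mbnl3 and Rwdd3 lost theirs under limma-voom. Emcn, Mbnl3, Nap1l5 and Rwdd3 lost theirs without the low-count filter, and Nap1l5, Rwdd3 and Scand1 with the unstranded column.

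The macrophage-labelled libraries carried high levels of endothelial transcripts. In those labelled wild type on the control diet (n = 6) Pecam1, an endothelial junction gene, stood at 1722 ± 198 CPM against 235 ± 11.8 in eWAT (n = 7), Kdr, a receptor for vascular growth factor, at 1939 ± 492 against 216 ± 19.5, and Cdh5, endothelial cadherin, at 822 ± 68.4 against 317 ± 26.4. The genes of the 3 sort markers were lower than in whole eWAT: Adgre1, which encodes F4/80, at 29.6 ± 21.3 against 74.8 ± 9.78, Itgam, which encodes CD11b, at 6.46 ± 5.65 against 19.1 ± 3.8, and Fcgr1, which encodes CD64, at 1.5 ± 0.41 against 6.16 ± 4.13. The 10 endothelial markers had a median ratio of 8.34 to eWAT and were all higher, the 15 pan-macrophage markers a median ratio of 0.55 with 2 higher, and the 18 adipocyte genes one of 0.027. Immediate early and dissociation-stress genes had a median ratio of 121, with Egr1 at 11873 ± 1215 against 33.7 ± 15.3 CPM and Fos at 8198 ± 521 against 12.7 ± 4.98. Tissue and library kit cannot be told apart in these ratios, and no test was made between the tissues. The share of each cell type in a macrophage-labelled library was not measured. In the comparisons below, changes in cell type markers may thus reflect that share or expression within the cells.

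**Figure D4:**
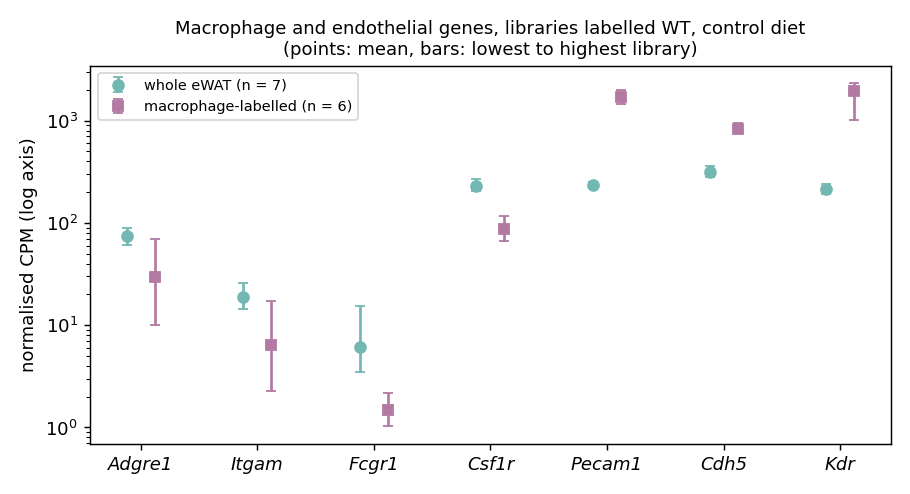
Levels (CPM, log axis) of macrophage and endothelial genes in eWAT (n = 7) and macrophage-labelled (n = 6) libraries labelled wild type on the control diet, each point a mean and each bar the span from the lowest to the highest library. Pecam1 averages 235 CPM in eWAT and 1722 CPM in the macrophage-labelled libraries, while Csf1r averages 232 and 87.2 CPM.

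In the macrophage-labelled libraries on the control diet (n = 6 and 6) adipocyte genes were lower with the knockout label. Of 18 members 4 were lower, and 11 lower with 1 higher adjusted over the list alone. Cidec went from 59.3 ± 10.5 to 31.4 ± 2.61 CPM (-0.93 ± 0.11), Cfd from 91.9 ± 16.2 to 32.4 ± 13.8 CPM (-1.51 ± 0.24) and the adrenergic receptor gene Adrb3 from 7.41 ± 1.47 to 3.48 ± 0.990 CPM (-1.10 ± 0.18). The list had adjusted p = 8.4e-20 and adjusted p = 0.015 with an estimated correlation. In the libraries labelled wild type its genes had a median ratio of 0.027 to eWAT. Adipocyte RNA carried over into the libraries was not separated from expression in the sorted cells. Cyp2e1, a cytochrome gene (-2.11 ± 0.35), and Ifi27l2a (-0.97 ± 0.16) were lower, and Zfp949 (0.73 ± 0.11) and the translation factor gene Eif4a2 (0.51 ± 0.05) higher. Resident macrophage genes and T cell genes had no member past the test over all genes (1 higher and 2 lower adjusted over the list alone) and list tests of adjusted p = 0.00089 each, upwards and downwards, or 0.85 each as adjusted p with an estimated correlation. Red blood cell genes (0.021) and immediate early and dissociation-stress genes (0.011) also passed downwards, with no member called and adjusted p = 0.85 each with an estimated correlation. In all 5 genes were higher and 9 lower of 17067. The DESeq2 Wald test gave 21 and 76 and limma-voom 9 and 24. The replicate block gave 3 and 12 and ended the call of Zfp949. The count was 4 to 7 when any single library other than wild type replicate 2 was left out and 18 without that one: 7 without wild type replicate 1, 5 without knockout replicates 1 or 4, 6 without knockout replicate 3 and 4 without each of the rest. Cidec and Eif4a2 kept their calls in all 12 of these runs. Cyp2e1 kept its call in none, Zfp949 only without wild type replicate 2, Adrb3 only without that one or knockout replicate 3, Cfd only without knockout replicate 3 and Ifi27l2a only without knockout replicate 4, with adjusted p from 0.063 to 0.16 elsewhere. With all 4 macrophage-labelled groups in one fit the calls of Cyp2e1, Eif4a2 and Zfp949 ended, without the low-count filter those of Cfd and Cyp2e1, and with DESeq2 size factors that of Cyp2e1. Wild type replicates 2 and 3 had 17.1% and 14.6% of reads unmapped, against 9.73% to 12.2% in the other 10 libraries, and replicate 2 a GC slope of 0.25, and the list was not tested without them. Cidec kept its call without either one. The changes followed GC content (Spearman correlation -0.35 across genes), and with a GC offset 5 genes passed and the calls of Adrb3, Cfd, Cyp2e1, Eif4a2 and Ifi27l2a ended.

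On the ketogenic diet (n = 3 and 3) edgeR called no gene of 17067 between the macrophage-labelled libraries of the 2 genotype labels, 520 had an unadjusted p under 0.05, DESeq2 called 14 and limma-voom 0. Without the low-count filter 26 were higher and 77 lower, and with the replicate block 7 were lower. Pan-macrophage markers had a median log2 fold change of -0.45 with the knockout label, 11 of 15 lower adjusted over the list alone and none over all genes (list adjusted p = 6.5e-31; 0.25 with an estimated correlation). Lipid-associated macrophage genes (5 of 15 lower adjusted over the list alone, 9.5e-11) and resident macrophage genes (0 of 14, 1.4e-05) also pointed down, as did mesothelial genes (1 of 9, 4.6e-09), which mark another cell type, while adipocyte genes (0 of 18, 3.9e-06) and B cell genes (0 of 12, 0.00044) pointed up. These became adjusted p = 0.25, 0.25, 0.32, 0.57 and 0.41 with an estimated correlation. Lysosomal (0.00040), MHC class II (0.00069) and inflammatory cytokine genes (0.00074) passed downwards with no member called, and came to adjusted p = 0.25, 0.64 and 0.25.

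The genotype labels of these 6 libraries stand in doubt. Of 14002 genes examined, 3 had no overlap between the genotype labels, in the same direction, in eWAT on either diet and in the macrophage-labelled control-diet libraries: Gm11868 (ENSMUSG00000050550, chromosome 4, 18844202 to 18845679), Zfp949 (ENSMUSG00000032425, chromosome 9, 88548020 to 88571061) and Eif4a2 (ENSMUSG00000022884, chromosome 16, 23107444 to 23114136), a selection made after the values were seen. In the macrophage-labelled ketogenic libraries wild type replicates 1 and 2 and knockout replicate 1 lay on the knockout side for all 3 genes. Wild type replicate 3 and knockout replicates 2 and 3 lay on the wild type side. Gm11868, for example, stood at 4.67, 4.55 and 0.98 CPM in wild type replicates 1, 2 and 3 and at 3.89, 1.3 and 1.02 CPM in knockout replicates 1, 2 and 3. In the control-diet libraries it ranged from 0.81 to 1.26 (wild type) and 3.74 to 4.99 CPM (knockout). With wild type replicates 1 and 2 and knockout replicates 2 and 3 left out, 2 genes were called, in a fit of all 4 groups that assumes the single library left in each ketogenic group to vary like the other groups.

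**Figure D5:**
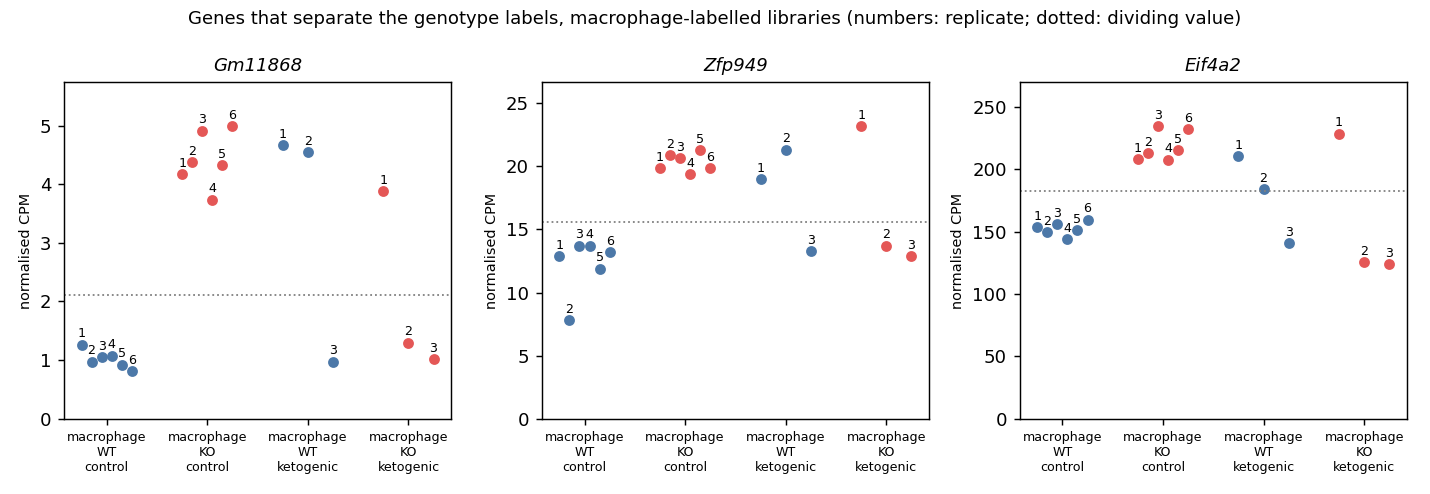
Levels (CPM, vertical axis) of Gm11868, Zfp949 and Eif4a2 in each macrophage-labelled library by group, each point a library and the line the value that divides the control-diet genotype labels. On the ketogenic diet wild type replicates 1 and 2 lie above the lines at 2.12, 15.6 and 182 CPM and knockout replicates 2 and 3 below them.

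In macrophage-labelled libraries labelled wild type, 3 ketogenic were compared with 6 control. Fatty acid oxidation genes rose, 6 of 18 over all genes and 12 adjusted over the list alone, with Pdk4 from 26.5 ± 4.54 to 81.2 ± 19.6 CPM (1.61 ± 0.16) and Hadhb (0.62 ± 0.09). Cholesterol synthesis genes rose in 5 of 14 (8 adjusted over the list alone), with Insig1 (0.57 ± 0.09) and squalene epoxidase, Sqle (0.77 ± 0.14). Clock genes rose in 6 and fell in 1 of 12 (8 and 1 adjusted over the list alone), with Dbp (2.03 ± 0.40) and Ciart (1.37 ± 0.25) higher and Arntl (-1.15 ± 0.20) lower. The lipid droplet gene Plin2 rose by 0.98 ± 0.10, and the haemoglobin gene Hbb-bs fell among red blood cell genes (-1.28 ± 0.26; 4 of 6 lower, and 5 with 1 higher adjusted over the list alone). The endothelial lipase gene Lipg (2.01 ± 0.43), Mmrn1 (1.94 ± 0.46), Hunk (1.83 ± 0.27) and Fam107a (1.82 ± 0.17) were further large rises. The chemokine gene Ccl8 (-2.52 ± 0.57), the lipocalin gene Apod (-2.08 ± 0.27), Fam124b (-2.08 ± 0.36), the lectin gene Cd209d (-1.93 ± 0.27) and Casq2 (-1.87 ± 0.13) were the largest falls. Txnip differed by 0.40 ± 0.11 (adjusted p = 0.078), and passed under DESeq2 (0.026), limma-voom (0.027), without control replicate 1 (0.047) and with both genotype labels together (0.0084).

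In this comparison 307 genes were higher and 316 lower of 17687. The split was 785 and 800 with the DESeq2 Wald test and 1319 and 1133 with limma-voom. It was 1348 and 1589 with all 4 groups in one fit and 1386 and 752 with the replicate block. The lists of fatty acid oxidation (1.0e-08), cholesterol (4.5e-07), clock (2.1e-05) and red blood cell genes (0.00061) passed, and came to adjusted p = 0.17, 0.52, 0.49 and 0.59 with an estimated correlation. Pan-macrophage genes passed downwards (median -0.50, 0 of 15 called, 0.021) and extracellular matrix genes upwards (1 of 14, 0.0070), each at adjusted p = 0.93 with an estimated correlation. The count was 17, 177 and 138 without ketogenic replicates 1, 2 and 3, 1685 without control replicate 2, and 401, 321, 347, 278 and 382 without control replicates 1, 3, 4, 5 and 6. Of the 18 genes named with a call Fam107a, Casq2, Pdk4 and Plin2 kept it in all 9 runs, and the other 14 lost it in at least 1 (adjusted p from 0.050 to 0.26), all 14 without ketogenic replicate 1. Without the low-count filter Ccl8, Dbp, Hbb-bs, Lipg and Mmrn1 lost theirs, and with the GC and length offset Ccl8, Hadhb and Mmrn1. Without ketogenic replicates 1 and 2, whose labels are in doubt, 1 ketogenic library is left against 6, and the spread comes from the controls alone. That fit called 5 genes, Casq2 among the 18, and the fall in number says nothing about the labels. With both genotype labels together (6 ketogenic, 12 control), which needs no genotype label, 5348 genes passed and all 18 kept their calls.

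In macrophage-labelled libraries labelled knockout (3 ketogenic, 6 control) pan-macrophage markers fell in 14 of 15 (15 adjusted over the list alone), with the complement genes C1qa (-1.32 ± 0.11) and C1qc (-1.14 ± 0.09) and with Csf1r (-0.94 ± 0.07). Resident macrophage genes fell in 8 of 14 (10 adjusted over the list alone), among them Mrc1 (-1.43 ± 0.14), Clec10a (-1.43 ± 0.16) and Cbr2 (-1.36 ± 0.17). Adipocyte genes rose in 11 and fell in 1 of 18 (13 and 1 adjusted over the list alone), with Plin4 (1.97 ± 0.13), Acsl1 (0.56 ± 0.04) and Cidec (0.99 ± 0.12). A changed share of macrophages or of adipocyte RNA in the libraries was not separated from changed expression. Fatty acid oxidation genes rose in 12 of 18 (13 adjusted over the list alone), including Cpt1a, the gate of mitochondrial fatty acid entry (0.49 ± 0.05), and Hadhb (0.65 ± 0.07). Clock genes rose in 7 and fell in 1 of 12 (8 and 2), including Ciart (2.01 ± 0.15), Per2 (1.86 ± 0.28) and Per1 (0.63 ± 0.12). Pck1, of glyceride and glucose synthesis (3.33 ± 0.43), Cyp1a1 (3.30 ± 0.28), Mmrn1 (2.31 ± 0.35) and Cyp2e1 (2.11 ± 0.52) rose most beside Ciart. Ccl8 (-3.67 ± 0.40), Serpinb2 (-3.48 ± 0.98), the B cell chemokine gene Cxcl13 (-3.10 ± 0.32), the acute-phase gene Saa3 (-3.01 ± 0.50) and the lipoxygenase gene Alox15 (-2.64 ± 0.69) fell most. Txnip differed by 0.30 ± 0.15 (adjusted p = 0.19), and passed without control replicate 3 (0.044) and with both genotype labels together (0.0084).

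Here 1889 genes were higher and 1694 lower of 17693. The lists had adjusted p = 2.0e-29 for pan-macrophage, 4.1e-12 for adipocyte, 4.3e-11 for resident macrophage, 2.5e-09 for fatty acid oxidation and 1.8e-05 for clock genes. These became adjusted p = 0.12, 0.17, 0.17, 0.25 and 0.17 with an estimated correlation. Without ketogenic replicates 2 and 3, whose labels are in doubt, 1 ketogenic library is left against 6, and the spread comes from the controls alone. That fit called 1044 genes, not Alox15, Cyp2e1, Per1, Per2, Saa3 or Serpinb2, and is no test of these calls. With both genotype labels together Cidec, Cyp1a1 and Cyp2e1 lost theirs, and with all 4 groups in one fit, which called 1505 genes, so did Alox15, Cxcl13, Saa3 and Serpinb2. Alox15 and Serpinb2 also lost theirs under limma-voom, with the replicate block and, like Cyp2e1, without the low-count filter. Serpinb2 lost its call without control replicates 4 or 6 or ketogenic replicates 1 or 2 (adjusted p from 0.056 to 0.13), Alox15 without control replicate 4 or any ketogenic replicate (0.052 to 0.11) and Cyp2e1 without ketogenic replicate 3 (0.11).

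The interaction of genotype label and diet in the macrophage-labelled libraries (18 libraries) had no call by edgeR of 18566 genes, with 726 at an unadjusted p under 0.05, 16 by DESeq2 and 6 by limma-voom. Adipocyte genes had a median of 0.74, 10 of 18 positive adjusted over the list alone and none over all genes (list adjusted p = 3.2e-22; 0.015 with an estimated correlation). Pan-macrophage genes had a median of -0.43, with 1 of 15 negative adjusted over the list alone (list adjusted p = 3.1e-09; 0.43 with an estimated correlation). Txnip had -0.09 ± 0.20 (adjusted p = 0.96). This contrast rests on the 6 ketogenic libraries whose genotype labels are in doubt.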

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

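The tests on the macrophage-labelled libraries below were chosen only after the result was seen. Those on Arrdc4, on the segment around Adipoq and on regrouped libraries were written before their own values were seen. The tests on Arrdc4 and on the segment address a pattern already seen.

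Txnip was higher in the eWAT libraries labelled knockout. Arrdc4, the other arrestin gene that MondoA and ChREBP switch on with glucose, was higher as well (log2 fold change 0.31 on the control diet). In the macrophage-labelled control-diet libraries Arrdc4 went from 102 ± 12.9 to 134 ± 8.87 CPM with the knockout label, while Txnip did not pass its test. In eWAT on the ketogenic diet Txnip was called, and 0 of 13 genes of the list that holds Arrdc4 were. The 2 genes thus did not move together throughout. A response of these factors to glucose stays open, in whichever genotype. An exchange of the labels as a whole would put the segment around Adipoq, a promoter often used for adipocyte-specific recombination, on the other side. The genes within 150 kb of Adipoq, without Adipoq and Eif4a2, had a median of 0.26 in the macrophage-labelled control-diet libraries (bootstrap interval 0.04 to 0.53, from resampling these genes and not the libraries), which reaches below the bound of 0.2 set in advance. In eWAT their medians were 0.46 on the control diet (7 of 8 positive, 3 called) and 0.29 on the ketogenic diet (5 of 6 positive, 2 called), opposite to what an exchange predicts if that promoter was used, but the labels do not name the promoter, so exchanged and correct labels cannot be told apart. A transcript that is counted although part of the gene is lost may also be the source, and counts over whole genes cannot test that.

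The macrophage-labelled libraries carried more endothelial than macrophage transcript. All 10 endothelial markers were higher than in eWAT, which itself expresses all 10, the median ratio of the pan-macrophage list to eWAT was 0.55 (interval 0.38 to 0.73), and the ratio of the endothelial to the pan-macrophage median was 15.2 (interval 8.70 to 30.3). Both intervals come from resampling the genes of a list and leave out the variation between libraries. Endothelial cells among the sequenced cells are a candidate explanation, although the sort for F4/80, CD11b and CD64 should remove them. Pure macrophages that express endothelial genes should carry more macrophage transcript than whole eWAT. The pan-macrophage median was lower, with 2 of 15 markers higher, which argues against them unless the kit lowers these genes. A kit that shifts all genes alike would move both lists by a like ratio, and the ratio of 15.2 argues against that. Each tissue has its own kit and the ratios restate the pattern, so a kit that acts differently on each gene cannot be told apart from endothelial cells.

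In the macrophage-labelled ketogenic libraries 4 of 6 lay on the side of the other genotype label for the 3 separating genes, 2 under each label. An exchange of labels among the 6 libraries would give that number, and may account for the absence of calls between the genotype labels. A genotype difference that the ketogenic diet removes would leave the 6 libraries alike. For these 3 genes they lay on both sides of the dividing values, which argues against it. Their variance was a median of 34.0 times that within the control-diet label groups (95% interval 8.02 to 225, that of Eif4a2). The genes were chosen for not overlapping in those groups, which favours a small variance there. The ratio thus restates the pattern, and its interval is no calibrated test. Singly the ratio was 34.6 for Gm11868, 34.0 for Eif4a2 and 2.84 for Zfp949 (interval 0.67 to 18.8, which alone would not decide), against a median of 0.50 over 13991 genes. The exchange rests on 3 genes chosen from the same series and stays a hypothesis.

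Regrouping the libraries tests whether chance can be excluded for the counts. By a share of splits under 0.05 it can for eWAT on the ketogenic diet (1 of 100 splits, the real one, gave as many genes, 512 against 1 in the highest other). It can likewise for eWAT labelled wild type by diet (1 of 100, 8373 and 4559), eWAT labelled knockout by diet (1 of 100, 6518 and 1327) and the eWAT interaction (1 of 100, 1425 and 590). For macrophage-labelled libraries it can by diet in the wild type label (1 of 84, 623 and 387) and in the knockout label (1 of 84, 3583 and 66). Diet coincides with library set, so the counts by diet cannot be credited to diet. In eWAT on the control diet 2 of 100 splits gave as many genes, the real one with 2677 and another with 2838. That share is under 0.05, but the other split called more genes than the real one. A structure of those libraries apart from the label thus gives as many. The same libraries enter the eWAT interaction, so that structure can add to its 1425 calls. The splits were made without a GC offset, with which the interaction had 252 calls. The macrophage-labelled control-diet comparison had 2 of 100 splits with as many genes as the real 14, and the other called 1326, which points to a structure of the samples. In the macrophage-labelled interaction all 100 splits gave 0, as the real one did. With a real count of 0 every split gives at least as many, so regrouping cannot test it. The macrophage-labelled ketogenic comparison has 10 splits, too few for a share under 0.05. Its real count was 0 as well, with 3 in the highest other, so the same limit holds there.

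Of 313 pairs of a named gene and a group, 19 held 1 library that stood far from the rest, and chance gives about 1 in 20. In eWAT on the control diet these were Tek in knockout replicate 6 (90.3 CPM, the others 105 ± 2.55), Nap1l5 in knockout replicate 2 (3.17, others 1.3 ± 0.35), Fcer1g in wild type replicate 4 (34.5, others 24.0 ± 1.41) and Scand1 in wild type replicate 1 (8.57, others 1.84 ± 1.32). In eWAT libraries labelled wild type on the ketogenic diet they were Ptx3 (4.44) and Acadl (276) in replicate 1, Fasn in replicate 2 (1576, others 833 ± 154), Il1rn (6.04) and Lgals3 (127) in replicate 3 and Efcab8 in replicate 8 (9.55). Those labelled knockout on that diet had Slc25a20 (71.6), Serpina3k (1.08) and Lrtm1 (1.63) in replicate 5, Cyp2f2 in replicate 3 (2.22) and H2-DMb1 in replicate 6 (20.6). In the macrophage-labelled control-diet libraries they were Zfp949 in wild type replicate 2 (7.80, others 13.1 ± 0.76), Adrb3 in wild type replicate 3 (10.3) and knockout replicate 3 (5.43), and Apod in wild type replicate 3 (108, others 56.8 ± 8.19).

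The effect of the genotype label differed between the diets in eWAT for 1425 genes by the interaction test, and for 252 with a GC offset. The offset ended the calls of 11 of the 15 genes the report names for it, and Arg1, Junb, Insig1 and Kdr kept theirs. Among the genes named in any eWAT comparison the values (log2, ketogenic minus control) were positive for Arg1 (2.83), Scand1 (2.38), Hist1h4h (2.20), Junb (1.98), Crlf2 (1.76), Ifi27l2a (1.42), Cfd (0.96), C1qa (0.88), C1qc (0.86), Srebf1 (0.82), Acads (0.74), H2-DMb1 (0.70), C1qb (0.68) and Cbr2 (0.45). They were negative for Rwdd3 (-1.31), Insig1 (-1.04), Nap1l5 (-0.98), Mbnl3 (-0.84), Scd1 (-0.69), Acaca (-0.59), Msmo1 (-0.51), Kdr (-0.47) and Emcn (-0.31).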

How the results depend on the processing

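The GC offsets and the fits without libraries of doubtful label were chosen only after the result was seen. Counts of called genes moved by over 1.5 times as follows, and the cause was not tested. With a GC offset eWAT on the control diet gave 1211 (1252 with length), the eWAT interaction 252 (260) and the macrophage-labelled control-diet comparison 5 (4). DESeq2 gave 1047 in eWAT on the ketogenic diet, 97 and 14 in macrophage-labelled libraries on the control and ketogenic diets, 1585 in the wild type label by diet and 16 in their interaction, and limma-voom gave 33, 2452 and 6 in the control-diet, wild type by diet and interaction comparisons. Without the low-count filter the ketogenic comparisons gave 331 (eWAT) and 103 (macrophage-labelled). With all 4 groups in one fit the macrophage-labelled libraries gave 9 on the control diet and 2937 and 1505 by diet in the wild type and knockout labels. The replicate number as a block, although the rule for pairing was not met, gave 1586 in eWAT on the ketogenic diet and 7, 2138, 1569 and 10 in the macrophage-labelled ketogenic, wild type by diet, knockout by diet and interaction comparisons. Without libraries of doubtful label the ketogenic comparison gave 2, the wild type diet comparison 5 and the knockout diet comparison 1044, each with a single library left per ketogenic group, so these show no effect of the labels. Both genotype labels together gave 5348. With DESeq2 size factors the eWAT interaction was 1021 positive and 416 negative.

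Leaving out 1 library at a time gave 1925 to 3287 genes in eWAT on the control diet and 205 to 788 on the ketogenic diet. In macrophage-labelled libraries it gave 4 to 18 (control diet), 0 to 1 (ketogenic; 1 without wild type replicate 2), 17 to 1685 (wild type by diet), 2452 to 3361 (knockout by diet) and 0 to 4 (interaction; 4 without knockout ketogenic replicate 1 and 1 without wild type ketogenic replicate 3). Txnip changed sign, each time without passing the test, in macrophage-labelled libraries. On the control diet it had -0.017 without knockout replicate 3, and at most 0.14, without wild type replicate 1. On the ketogenic diet it had 0.027 with limma-voom, 0.04, 0.10 and 0.004 without wild type replicate 1, knockout replicate 2 and knockout replicate 3, 0.30 without the libraries of doubtful label, and at least -0.17, without knockout replicate 1. In the interaction it had 0.0088 with limma-voom, 0.027 without knockout ketogenic replicate 2, 0.22 without the libraries of doubtful label and at least -0.25, without knockout ketogenic replicate 1.

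Of 1594 reruns of the 175 named gene calls 1446 kept the call, 148 lost it and 0 reversed, and without the GC offsets 1145 of 1244 kept it. Both tallies include the fits with a single ketogenic library. Leaving out 1 library kept 1031 of 1321, with 64 of 106 calls kept in every run. Of 86 list calls an estimated correlation kept 2, adipocyte genes in the macrophage-labelled control-diet comparison and interaction, fry 39, DESeq2 size factors 85 and the GC offset 80, and none reversed.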

Other observations

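All tests in this part on chromosome segments were written before their own values were seen, but for a pattern already seen, genes higher with the knockout label in both tissues. The 3 separating genes were chosen after.

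On the ketogenic diet further lists passed their test in the direction of the knockout label in eWAT at the preset correlation, and none with an estimated one. Monocyte and neutrophil genes had 1 of 8 higher (3 adjusted over the list alone; list adjusted p = 0.0057, and 0.15 with an estimated correlation), dendritic cell genes 1 of 7 (2; 0.041, and 0.32), T cell genes 0 of 11 (1; 0.043, and 0.43) and progenitor and fibroblast genes 0 of 9 (1; 0.0087, and 0.38). The unfolded protein response (0.012, and 0.43) and immediate early genes (0.033, and 0.48) had no member past the test. Hypoxia genes (0.033, and 0.15) and glycolysis genes (0.046, and 0.48) passed towards the wild type label, with 1 of 7 and 0 of 17 members lower.

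In the macrophage-labelled libraries on the ketogenic diet T cell genes had 1 of 13 members higher in the wild type label (list adjusted p = 0.039; 0.87 with an estimated correlation) and 6 of 13 in the knockout label (1.8e-05; adjusted p = 0.45 with an estimated correlation). In the wild type label interferon genes had 2 of 15 higher (0.0020; adjusted p = 0.52 with an estimated correlation). In the knockout label MHC class II genes had 5 of 9 lower (0.0012; adjusted p = 0.53 with an estimated correlation), inflammatory cytokine genes 3 of 16 (0.021; adjusted p = 0.53) and lysosomal genes 5 of 15 (0.026; adjusted p = 0.53), while cholesterol synthesis genes had 3 of 14 higher (0.0012; adjusted p = 0.55). The genotype labels of the ketogenic libraries in these comparisons are in doubt. Crisp1, a transcript of the epididymis, stood at 21.8 CPM in knockout ketogenic replicate 1 and 6.85 CPM in wild type ketogenic replicate 3.

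The 3 separating genes, higher with the knockout label in both tissues, lie on 3 chromosomes. Extra copies of a segment of chromosome 16 around Adipoq could raise Eif4a2, which lies near it. The median of the 8 other genes within 150 kb was 0.26 in the macrophage-labelled control-diet libraries, 0.46 in eWAT on the control diet and 0.29 (6 genes) on the ketogenic diet. In the first the interval, from resampling these genes and not the libraries, was 0.04 to 0.53, which leaves extra copies open. A segment of chromosome 9 that differs between the genotypes might account for Zfp949, but genes within 5 Mb of it were called in eWAT on the control diet at an odds ratio of 0.77 (95% interval 0.27 to 1.82; 6 of 47 against 2671 of 16699), which is too wide to decide.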
